A study of Mus musculus with 12 samples.

How the data were processed

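RNA was measured in 12 libraries of neural stem cells grown from C57BL/6J mouse embryos at embryonic day 14.5, with 3 libraries in each of 4 groups: wild type and knockout of the E12 line, and wild type and knockout of the E47 line. The wild-type cells came from litter mates of the knockout animals, per the labels. Libraries were made with a stranded mRNA kit, per the labels' protocols. Reads were handled with STAR 2.5 on genome build mm9 and compared with DESeq2 and DESeq, per the submitters' processing notes; the annotation release is not given in the sources used here.

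The authors deposited whole-number read counts per gene for each library in 3 versions, namely reads of both strands, reads of the sense strand and reads of the opposite strand, in the layout of STAR's gene counting, with reads that map to several places left out. Opposite-strand counts held 97.1 to 97.2% of the strand-assigned gene reads in every library, as a kit that reads the opposite strand gives, and were used for all tests. For each line the authors also deposited 1 table of their own comparison with normalized signal per library and its mean, log2 fold changes with standard errors, a score, which is the fold change over its standard error, and p-values with adjusted p-values by the authors. In those tables, the deposited signal equals the both-strand counts divided by 1 factor per library to within a relative difference of 5.11e-15, and genes of low mean signal are left out. Repeated entries of a gene (88 in the E12 table and 90 in the E47 table) were used once.

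Gene names came from a mouse reference of another build, GRCm38, by Ensembl ID, which named 32897 of the 37620 IDs; the deposited tables named 10 more and 4713 kept their ID. That reference was used only for names, chromosomes, the order of neighbouring genes and transcript sequences, and no coordinate was taken from it. Counts per gene cannot separate E12 from E47, which are splice forms of Tcf3.

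Counts were tested in R 4.3.3 with the quasi-likelihood (QL) F test of edgeR 4.0.16, with its low-count filter by group, TMM normalization and two-sided p-values adjusted by Benjamini-Hochberg (BH); a gene was called at an adjusted p under 0.05. Each line was fitted with its own 6 libraries. The difference between the knockout effects of the lines was tested as an interaction in all 12 libraries, and the wild types of both lines were set against each other in their 6 libraries. Log2 fold changes are fitted values with a prior count of 0.125, given with a standard error taken as the fold change divided by the root of F. CPM values are TMM-scaled and given as mean ± SD over the 3 libraries of a group; values per library come from scaling all 12 together. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by BH over the lists of 1 comparison. Camera with an estimated correlation and fry were run beside it; fry's directional p tests whether a list's genes move one way on balance, and its mixed p whether they change in either direction. Lists with fewer than 2 tested members in a comparison were not tested there.

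The 31 lists (625 entries, 616 found) and the rule for naming genes were fixed before the data were examined. The lists cover bHLH factors, stem cells, intermediate progenitors, neurons, deep and upper cortical layers, CDK inhibitors, proliferation, ventral, dorsal and posterior identity, astrocytes, oligodendrocytes, microglia, endothelium, mesenchyme and meninges, erythroid cells, the Notch, Wnt, BMP and TGF-beta, and Sonic hedgehog pathways, axon guidance, extracellular matrix, immediate early genes, interferon response, hypoxia and glycolysis, ER stress, p53 targets, cholesterol synthesis, ribosomal proteins and sex-linked genes. Sox1, Pou3f2, Cdkn2d, Lhx8, Hoxd4, Lhfpl3, Hbb-b1, Hbb-b2 and Hmgcs1 were not analysed here. The rule names Tcf3, Tcf4, Tcf12 and Cdkn1c in each comparison. It names up to 10 called genes with the largest rise and up to 10 with the largest fall in each line, with a mean of at least 1 CPM and no overlap between groups, and up to 5 of each in the other comparisons. From each list it names up to 4 called members, or the 2 with the highest mean CPM where none was called. Some genes that this rule names are not reported here. Other named genes were chosen after their values were seen, and are said to be so.

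Depth ranged from about 34515300 to 56835800 gene reads per library. A floor of 3 reads corresponds to 0.0528 to 0.0869 CPM, and this floor and the counting intervals cover counting error only. No pair of libraries of a group was alike within sampling noise: the chi-square of their counts divided by its degrees of freedom was 13.5 or more.

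The groups share replicate numbers, and no label says that a number marks a shared litter or day. Deviations from the group means correlated across genes at 0.30, 0.31 and 0.59 for the same-numbered E47wt and E47KO libraries, and at 0.33, 0.39 and 0.54 for E12wt and E47wt, which was taken as pairing from the data alone. Libraries of different number correlated at −0.46 to 0.23 and at −0.44 to 0.21 in these comparisons. With 3 libraries per group such a match can also arise by chance. A block for the replicate number left 2 genes called in the E47 knockout and 0 between the wild types.

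The tests were run on simulated counts drawn from the real means, library sizes and dispersions of each comparison, with 100 genes changed 2-fold and 100 changed 4-fold. In the E12 simulation of 14755 genes, edgeR QL recovered 87 and 99 of them and 19 of its 232 calls were false; DESeq2 recovered 91 and 98, with 39 of 257 false. In the E47 simulation of 14965 genes, edgeR QL recovered 50 and 95, with 8 of 153 false, and DESeq2 recovered 74 and 99, with 59 of 232 false. The interaction simulation of 15277 genes gave 40 and 84 recovered by edgeR QL, and that of the wild types (14892 genes) gave 87 and 100. With so many planted changes the BH cutoff was looser than in the real comparisons, where edgeR QL called 6 genes in E12 and 2 in E47. The recovered numbers therefore do not give the chance that a real change of that size was called. A list of 30 proliferation genes shifted by 0.5 on the log2 scale was found by camera in the E12 and E47 simulations. Simulated genes were drawn independently of each other, while the real list had an estimated correlation of 0.387 in E12 and 0.695 in E47. The simulation therefore cannot show how camera behaves with correlated genes.

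Alternatives fixed before the data were examined were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors (RLE) in edgeR, no low-count filter, a filter of 1 CPM in 3 libraries, both-strand counts, the replicate block, all 12 libraries in 1 fit, and each library left out in turn. Added after seeing the data were robust empirical Bayes, DESeq2 on both-strand counts, the sex of the embryo as a covariate, the E47 libraries with Y-linked reads alone, sex chromosomes left out, other numbers of neighbours around Tcf3, each library left out of the list, neighbour and correlation results, and the replicate block in the list tests between lines and between wild types. Windows around Tcf3 in megabases were planned and not run, because positions on the build of the counts were not used here; neighbour order took their place. The reference transcripts of Tdg and Gm9855 were aligned with blastn 2.17.0.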

Results

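Gene expression was measured by stranded mRNA sequencing in neural stem cells from midgestation mouse embryos, kept dividing in culture with the growth factors FGF-2 and EGF. E12 and E47 are basic helix-loop-helix (bHLH) transcription factors, known as E proteins, made by alternative splicing of the gene Tcf3. Cells lacking E12 (E12KO) and cells lacking E47 (E47KO) were each compared with wild-type cells of their own litter mates (E12wt and E47wt), with 3 libraries in each of the 4 groups. The libraries held about 34515300 to 56835800 reads on genes, and 18980 to 19617 genes had at least 1 read. A floor of 3 reads lay between 0.0528 and 0.0869 counts per 1e6 reads (CPM). The labels do not say whether the libraries of a group came from separate embryos or cultures. The p-values therefore measure the spread between these libraries only, which may be technical. In E47wt alone the libraries differed in sex-linked transcripts, as given below, so these did not all come from the same embryo. On the first principal component, with 38.0% of the variance, E12wt replicate 3 (−37.8) and E47KO replicate 2 (34.1) lay at the ends. Correlations between the libraries of a group were lowest for pairs with E47KO replicate 2 (0.957 and 0.973) and, among the E12 libraries, with E12wt replicate 3 (0.983 and 0.985).

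Tcf3 was expressed in every library of both knockouts. Its level was 76.4, 82.2 and 75.8 CPM in E12wt and 91.7, 72.9 and 101 CPM in E12KO, a log2 fold change of 0.18 ± 0.11 (SE, edgeR QL, BH-adjusted p = 0.605). In the E47 line it was 83.7, 75.4 and 97.2 CPM in wild type and 118, 114 and 108 CPM in knockout, 0.39 ± 0.12 on the log2 scale (edgeR QL, BH-adjusted p = 0.971). Counts over the whole gene take in both splice forms, so these values do not check the labels. The other E protein genes stayed close to 0: Tcf4 had log2 fold changes of 0.07 and −0.02 and Tcf12 of 0.00 and −0.09 in the E12 and E47 knockouts.

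**Figure D1:**
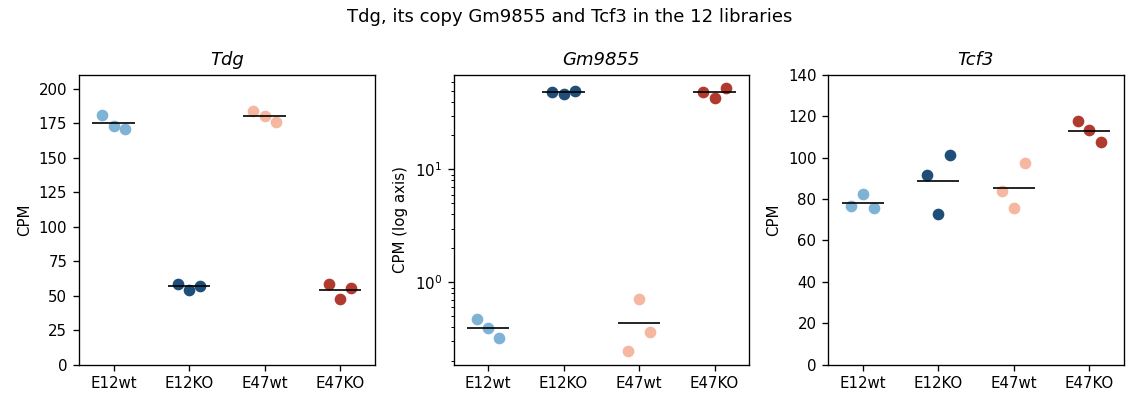
CPM of Tdg, its processed copy Gm9855 (log axis) and Tcf3 in the 12 libraries, one point per library, with a line at the mean of the 3 libraries of each group. Tdg lies between 47.5 and 58.6 CPM in the 6 knockout libraries and between 171 and 184 CPM in the 6 wild-type libraries.

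The first comparison asks which genes depend on E12 in dividing neural stem cells. Tdg, which encodes thymine DNA glycosylase, a base excision repair enzyme, fell from 174 ± 5.93 CPM in E12wt to 56.5 ± 2.13 CPM in E12KO (mean ± SD). Gm9855, a processed pseudogene that matches Tdg, rose from 0.396 ± 0.0782 to 48.2 ± 1.17 CPM. The matrix genes Col1a2, Bgn and Col1a1 fell from low levels: Col1a2, a chain of type I collagen, went from 2.02 ± 0.660 to 0.0491 ± 0.0254 CPM, the proteoglycan Bgn from 2.17 ± 0.446 to 0.196 ± 0.0271 CPM, and Col1a1, the other type I collagen chain, from 3.76 ± 0.252 to 1.05 ± 0.112 CPM. The transcript 2610203C22Rik rose from 0.460 ± 0.0497 to 2.43 ± 0.645 CPM.

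These were the 6 genes called of 14755 tested, 2 higher and 4 lower in E12KO. Their log2 fold changes with edgeR QL were 6.91 ± 0.13 for Gm9855 (ENSMUSG00000085666, BH-adjusted p = 7.3e-08), −1.63 ± 0.06 for Tdg (ENSMUSG00000034674, 9.26e-06), −3.45 ± 0.28 for Bgn (ENSMUSG00000031375, 0.00433), −5.28 ± 0.44 for Col1a2 (ENSMUSG00000029661, 0.00433), −1.83 ± 0.18 for Col1a1 (ENSMUSG00000001506, 0.0105) and 2.39 ± 0.28 for 2610203C22Rik (ENSMUSG00000079671, 0.0376). For each of these genes all 3 knockout libraries lay on the same side of all 3 wild-type libraries. Gm9855 and Tdg both lie on chromosome 10 of the GRCm38 reference, as does Tcf3. Because Gm9855 and Tdg are near-identical in sequence, the split of reads between them is uncertain. Col1a2 rests on 261 reads in E12wt and 6 in E12KO, a ratio of 41.4 with a 95% counting interval of 18.8 to 114. Bgn rests on 283 and 24 reads (ratio 11.2, interval 7.40 to 17.8) and Col1a1 on 490 and 129 reads (3.62, 2.97 to 4.43). Levels of Col1a2 differed by as much inside the wild types of the other line, at 3.92, 0.0428 and 0.0852 CPM in the 3 E47wt libraries. Gm9855 and Tdg were called under all 15 alternatives, Col1a2 and Bgn under 12, Col1a1 under 9 and 2610203C22Rik under 7. Without E12KO replicate 2 or without E12KO replicate 3, only Gm9855 and Tdg were called, and DESeq2 called 95 genes, among them these 6.

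Cdkn1c, which encodes the CDK inhibitor p57, was at 8.26 ± 1.03 CPM in E12wt and 5.29 ± 0.462 CPM in E12KO. With edgeR QL this log2 fold change of −0.64 ± 0.14 missed the threshold (BH-adjusted p = 0.418), and with DESeq2 it passed (BH-adjusted p = 0.0178). All 3 knockout libraries lay below all 3 wild-type libraries, as they did in one or the other direction for 13.8% of the genes tested, where chance gives 10%. At an unadjusted p under 0.05 there were 1322 genes, against 738 that chance gives. This count was 569 without E12KO replicate 3, 2158 without E12wt replicate 2 and 702 with all 12 libraries in the fit.

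**Figure D2:**
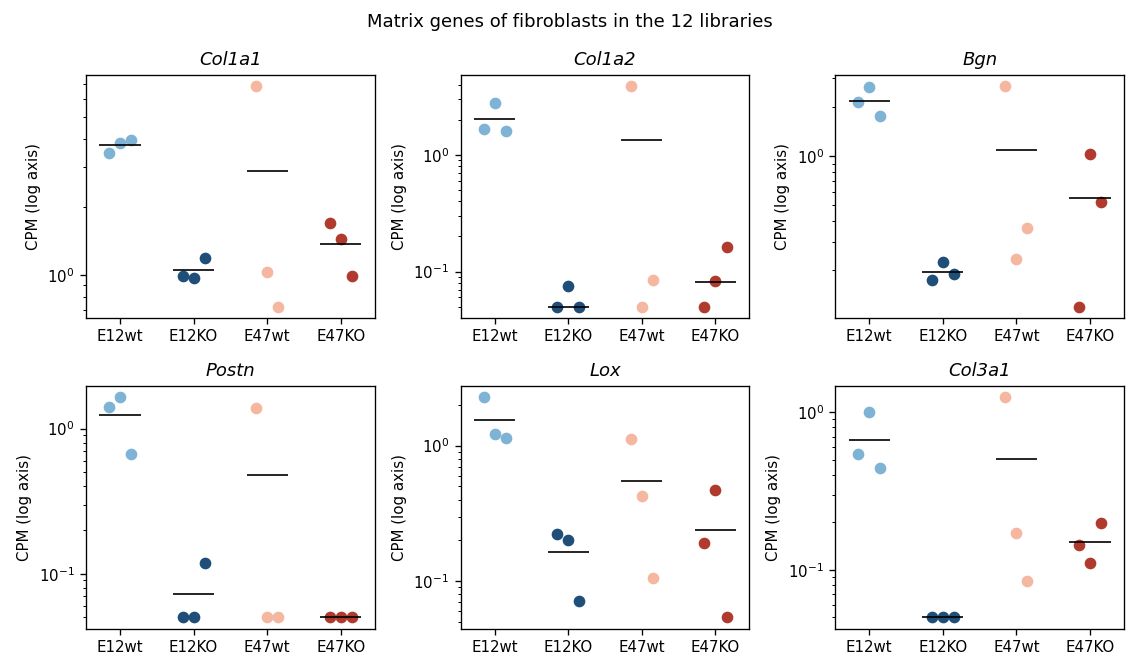
CPM (log axis) of 6 matrix genes in the 12 libraries, one point per library, with a line at the mean of each group; values under 0.05 CPM are drawn at 0.05. Replicate 1 of E47wt lies with the 3 E12wt libraries, and the other E47wt libraries lie with the knockouts for most of these genes.

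Among the lists fixed before the data were examined, 11 of 29 tested passed in the E12 knockout with camera's preset correlation, and 0 did after adjustment with an estimated correlation. Mesenchymal and meningeal markers were lower, with 7 of 10 below 0, a median log2 fold change of −0.87 and 2 members called (Col1a1 and Col1a2, camera, BH-adjusted p = 6.53e-05, p = 0.0236 with an estimated correlation). Adjusted over the list alone, 5 members were lower. Fry also passed this list (BH-adjusted p = 0.0358). Neuron markers were lower in 16 of 19 (median −0.26, camera, BH-adjusted p = 0.000141, p = 0.0489 with an estimated correlation), while their most abundant members, Map2 and Dpysl3, were at 0.03 and −0.22. Oligodendrocyte lineage markers were lower in 12 of 13 (median −0.59, camera, BH-adjusted p = 0.000595, p = 0.189 with an estimated correlation). Adjusted over that list alone, 4 were lower, and the abundant Olig1 and Olig2 were at −0.10 and −0.17.

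Genes of cholesterol synthesis and uptake were higher in 19 of 19, with a median of 0.27 (camera, BH-adjusted p = 2.44e-07, p = 0.174 with an estimated correlation). Cyp51, which encodes a demethylase of the pathway, was at 653 ± 107 CPM in E12wt and 793 ± 56.0 CPM in E12KO and was not called. ER stress genes were higher in 20 of 20 (median 0.19, camera, BH-adjusted p = 1.18e-05, p = 0.233 with an estimated correlation), with the chaperones Hspa5 and Hsp90b1 at 0.35 and 0.18. Immediate early genes were higher in 16 of 18 (median 0.32, camera, BH-adjusted p = 6.53e-05, p = 0.126 with an estimated correlation), with Klf6 at 0.45 and Jun at 0.13. Sonic hedgehog pathway genes were higher in 9 of 10 (median 0.15, camera, BH-adjusted p = 0.0195, p = 0.0474 with an estimated correlation), p53 targets in 14 of 18 (median 0.15, camera, BH-adjusted p = 0.0111, p = 0.226 with an estimated correlation) and astrocyte markers in 12 of 16 (median 0.27, 0.0192, p = 0.309 with an estimated correlation). Among their abundant members, Ptch1 was at −0.07, Cdon at 0.05, Ccng1 at 0.22, Cdkn1a at 0.40, Sparcl1 at 0.36 and Mlc1 at 0.39. Ribosomal protein genes were higher in 25 of 26, by a median of 0.06 (camera, BH-adjusted p = 0.0422, p = 0.565 with an estimated correlation, Rpl4 0.07, Rpl7 −0.01). Hypoxia and glycolysis genes were lower in 20 of 25 (median −0.19, camera, BH-adjusted p = 0.0146, p = 0.455 with an estimated correlation), with Pkm at 0.12 and Pgk1 at −0.09. Without E12wt replicate 3 the camera BH-adjusted p was 0.815 for hypoxia and glycolysis genes, 0.407 for astrocyte markers and 0.0595 for oligodendrocyte markers. Without E12KO replicate 1 it was 0.171 for astrocyte markers, and without E12KO replicate 2 it was 0.0838 for them and 0.102 for the hypoxia list, which also missed the threshold without E12KO replicate 1. For ribosomal protein genes it was 0.664 without E12wt replicate 1 and 0.878 without E12KO replicate 3, and it missed the threshold without E12KO replicate 1 too. That list passed in 3 of the 7 refits with a library left out or the replicate block. Sonic hedgehog genes reached 0.0886 without E12wt replicate 1 and 0.102 without E12KO replicate 2, as p53 targets did (0.102). Without E12KO replicate 2, 7 lists passed; the lists of neuron, mesenchymal, immediate early, ER stress and cholesterol genes passed in all 7 refits of the list tests with a library left out or the replicate block.

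Adjusted over each list alone, 1 member was higher among cholesterol genes, astrocyte markers and immediate early genes each, and 1 was lower among neuron markers, CDK inhibitors, bHLH factors and Wnt genes each. BMP and TGF-beta genes had 3 lower, and matrix genes 3 lower and 1 higher in the same way. Over all genes none of these was called except Col1a1 and Col1a2.

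The remaining lists did not pass in the E12 knockout with camera. Stem cell markers had a median of −0.03, a mean of 0.00 and a camera BH-adjusted p of 0.895, with Fabp7 at −0.14 and Ptprz1 at 0.07. Proliferation genes had a median of −0.02, a mean of 0.01 and a camera BH-adjusted p of 0.918, with Top2a, which untangles DNA in dividing cells, at 0.03 and Cdk4 at 0.01. Intermediate progenitor genes were below 0 in 11 of 13, with a median of −0.11 (camera, BH-adjusted p = 0.0569), Btg2 at −0.11 and Dll1 at −0.38. CDK inhibitors had a median of −0.04 and a mean of 0.01, and camera's direction was down (BH-adjusted p = 0.846); their abundant members Ccng1 and Cdkn1a were at 0.22 and 0.40. For bHLH factors the median was 0.04 (camera, BH-adjusted p = 0.823), with Tcf12 at 0.00 and Olig1 at −0.10. Notch genes had a median of 0.08 and a mean of −0.01 (camera, direction up, BH-adjusted p = 0.918), with Hes5 at −0.03 and Notch1 at 0.09.

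Deep-layer factors had a median of 0.04 and a mean of −0.02, and camera's direction was down (BH-adjusted p = 0.918), with Nfib at 0.13 and Etv1 at 0.04. Upper-layer factors were at a median of −0.01 (camera, BH-adjusted p = 0.850, Lmo4 −0.01, Pou3f3 −0.13) and ventral and interneuron genes at −0.07 (0.918). Dorsal telencephalon genes had a median of 0.01, a mean of −0.06 and camera's direction down (BH-adjusted p = 0.624), with Nr2f1 at −0.13. Posterior genes had a median of 0.44 (camera, BH-adjusted p = 0.490), with Otx1 at −0.22 and Gbx2 at −0.09.

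Wnt genes had a median of 0.07 and a mean of −0.03 (camera, direction up, BH-adjusted p = 0.663), with Ctnnb1 at 0.00 and Wnt5a at 0.25. BMP and TGF-beta genes were at a median of 0.03 (camera, BH-adjusted p = 0.934), with Smad5 at 0.19 and Bmpr1a at −0.04, while fry's test of change in either direction passed (BH-adjusted p = 0.0365). Axon guidance genes were at 0.04 (camera, BH-adjusted p = 0.553, Ncam1 0.06, Cdh4 0.16) and interferon-stimulated genes at 0.02 (0.581, B2m 0.23, Gbp3 0.23). Matrix genes as a class had a median of −0.03, a camera BH-adjusted p of 0.251 and 2 called members, Col1a1 and Col1a2. Fry's test of change in either direction passed for them (BH-adjusted p = 4.99e-05) and for the mesenchymal list (0.000115). Endothelial markers were at a median of 0.17 (camera, BH-adjusted p = 0.187, Kdr −0.15, Ramp2 0.17), and the 2 tested microglia markers, Cd68 and Laptm5, were at −0.40 and −0.31 (camera, BH-adjusted p = 0.490). No erythroid gene was tested, and of the sex-linked genes only Xist was, at 0.12.

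**Figure D3:**
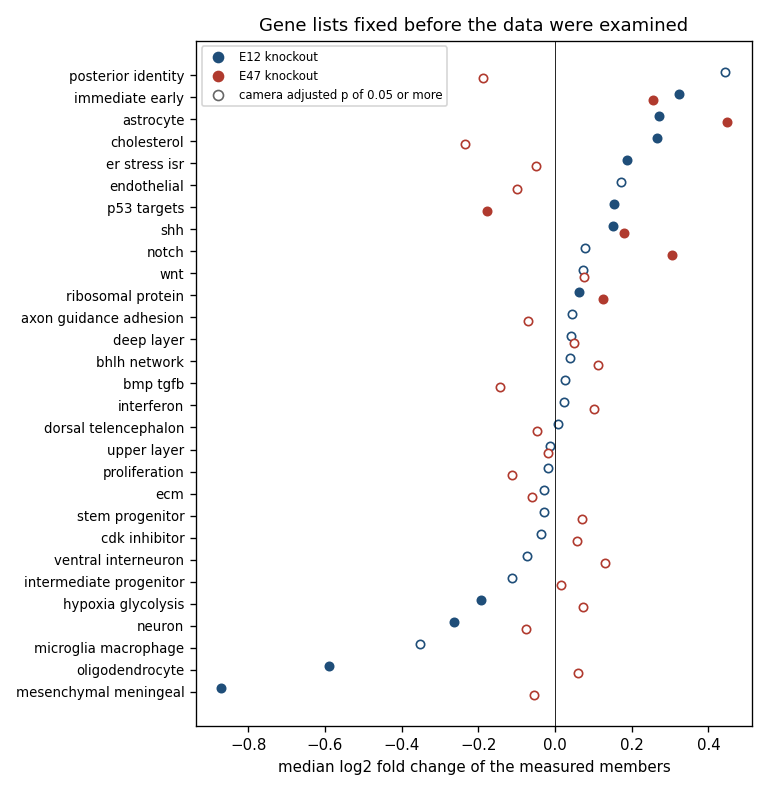
Median log2 fold change of the measured members of each list in the E12 and the E47 knockout; filled points have a camera BH-adjusted p under 0.05 with the preset correlation. Cholesterol, ER stress and p53 target genes lie on opposite sides of 0 in the 2 lines.

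The same question was asked of E47. Tdg fell from 181 ± 4.72 CPM in E47wt to 53.8 ± 5.68 CPM in E47KO, and Gm9855 rose from 0.442 ± 0.243 to 48.2 ± 4.56 CPM. These were the only genes edgeR QL called of 14965 tested, with log2 fold changes of −1.75 ± 0.11 for Tdg (BH-adjusted p = 0.00536) and 6.73 ± 0.35 for Gm9855 (0.00222). Cdkn1c was at 6.29 ± 2.19 CPM in wild type and 9.11 ± 6.14 CPM in knockout (log2 fold change 0.53 ± 0.50, edgeR QL, BH-adjusted p = 0.971), and its log2 fold change was −0.14 without E47KO replicate 2. The matrix genes that fell in E12KO were not called here: Col1a1 was at −1.07 ± 0.82 and Bgn at −0.98 ± 1.02, and Col1a2 was too low to be tested. At an unadjusted p under 0.05 there were 328 genes, against 748 that chance gives, and 7.88% of genes had no overlap between the groups, where chance gives 10%. This count was 149 without E47wt replicate 1, 179 without E47wt replicate 2, 511 without E47KO replicate 2 and 1416 without E47KO replicate 3. The same count was 493 with the replicate block and 787 with all 12 libraries in the fit.

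Sex-linked transcripts were spread unevenly over the E47 groups. Xist, the X inactivation transcript, was at 885 and 1115 CPM in E47wt replicates 1 and 3 and at 0.835 CPM in replicate 2, and between 0.252 and 0.791 CPM in the E47KO libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 245 CPM in E47wt replicate 2 and to 200 to 240 CPM in E47KO, but to at most 0.408 CPM in the other E47wt and all E12 libraries. Xist was not called by edgeR QL (log2 fold change −10.51 ± 2.32, BH-adjusted p = 0.971), and DESeq2 called it together with Plxdc2 (−0.69 ± 0.15) and Ccdc136 (0.52 ± 0.12), 5 genes in all. With sex as a covariate, Gm9855 stayed called and Tdg did not, at a log2 fold change of −1.76 ± 0.17 (edgeR QL, BH-adjusted p = 0.252). In the fits without that covariate that leave out a library in turn, its edgeR QL BH-adjusted p ran from 0.000859 to 0.102. The count was 0 without E47wt replicate 3, 1 without E47wt replicate 1 or E47KO replicate 1, and 7 without E47wt replicate 2, while over all 18 alternatives Tdg lay between −1.82 and −1.67 and Gm9855 between 6.07 and 7.27.

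**Figure D4:**
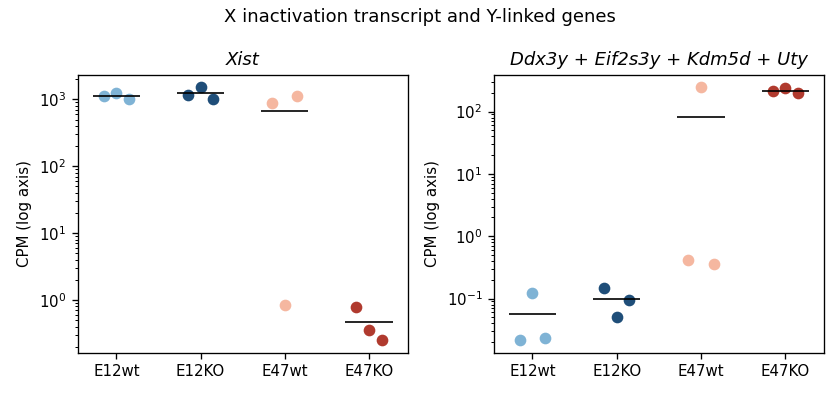
CPM (log axis) of Xist and of the sum of 4 Y-linked genes in the 12 libraries, one point per library, with a line at the mean of each group; sums under 0.01 CPM would be drawn at 0.01. Each library has reads on Xist or on the Y-linked genes, and the 2 kinds are mixed in E47wt alone.

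In the E47 knockout 7 of 29 lists passed with the preset correlation and 0 with an estimated one. Ribosomal protein genes were higher in 21 of 26 (median 0.12, camera, BH-adjusted p = 0.00174, p = 0.164 with an estimated correlation), with Rplp0 at 0.22 and Rpl4 at 0.00. Notch pathway genes were higher in 17 of 20 (median 0.30, camera, BH-adjusted p = 0.00853, p = 0.286 with an estimated correlation): the target Hes5 went from 377 ± 29.9 to 610 ± 316 CPM and Notch1 from 227 ± 9.78 to 327 ± 136 CPM, with a wide spread between the knockout libraries. Immediate early genes were higher in 15 of 18 (median 0.26, camera, BH-adjusted p = 0.00853, p = 0.0753 with an estimated correlation, Klf6 −0.06, Jun 0.09), astrocyte markers in 12 of 16 (median 0.45, 0.00892, p = 0.228 with an estimated correlation, Sparcl1 −0.12, Mlc1 0.25) and Sonic hedgehog genes in 8 of 11 (median 0.18, 0.0233, p = 0.0555 with an estimated correlation, Ptch1 0.10, Smo 0.18). Targets of p53 were lower in 16 of 18 (median −0.18, camera, BH-adjusted p = 0.00675, p = 0.128 with an estimated correlation, Ccng1 −0.28, Cdkn1a −0.27). Sex-linked genes passed as higher, with a median of 1.40, a mean of −0.97 and 4 of 5 above 0 (camera, BH-adjusted p = 0.0245, p = 0.104 with an estimated correlation, Eif2s3y 1.19). With the replicate block 6 lists passed, and 3 without E47wt replicate 1 or without E47KO replicate 3. With sex as a covariate, 4 passed. None of the 7 passed in all 8 refits. The camera BH-adjusted p of Notch genes was 0.0636 without E47wt replicate 3, 0.649 without E47KO replicate 2 and 0.112 with the sex covariate, and that of astrocyte markers 0.446, 0.399 and 0.109. Immediate early genes were at 0.0918 without E47wt replicate 1, 0.0852 without E47KO replicate 2, 0.193 without E47KO replicate 3 and 0.109 with the sex covariate. Sonic hedgehog genes were at 0.203 without E47wt replicate 1, 0.0703 without E47KO replicate 1, 0.193 without E47KO replicate 3, 0.0534 with the replicate block and 0.204 with the sex covariate. Targets of p53 were at 0.0960 without E47wt replicate 1 and 0.126 without E47KO replicate 3, and ribosomal protein genes at 0.0583 without E47KO replicate 1 and 0.0627 without E47KO replicate 3. Sex-linked genes missed the threshold with each library left out in turn except E47wt replicate 2 (up to 0.259 without E47KO replicate 3) and changed direction with the sex covariate.

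Cholesterol genes were below 0 in 15 of 19 in the E47 knockout and missed the threshold (median −0.24, camera BH-adjusted p = 0.0516), with Cyp51 at −0.32. The other lists did not pass. Neuron markers had a median of −0.08 (camera, BH-adjusted p = 0.0584, Map2 −0.14, Dpysl3 −0.04), axon guidance genes of −0.07 (0.0707, Ncam1 0.11, Cdh4 −0.06) and proliferation genes of −0.11 (0.104, Top2a −0.12, Cdk4 0.06). BMP and TGF-beta genes had a median of −0.14 (camera, BH-adjusted p = 0.127, Smad5 −0.19, Bmpr1a −0.11) and hypoxia and glycolysis genes of 0.07 (0.243, Pkm 0.07, Eno1 0.14). Stem cell markers had a median of 0.07 (camera, BH-adjusted p = 0.404), with Fabp7 at −0.17 and Ptprz1 at −0.27. Lists of bHLH factors (median 0.11, camera BH-adjusted p = 0.424, Tcf12 −0.09, Olig1 0.06) and CDK inhibitors (0.06, 0.515, Ccng1 −0.28, Cdkn1a −0.27) stayed near 0.

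Intermediate progenitor genes had a median of 0.01 (camera, BH-adjusted p = 0.688, Btg2 0.33, Dll1 0.28) and ER stress genes of −0.05 (0.688, Hspa5 −0.05, Hsp90b1 −0.09). Oligodendrocyte markers had a median of 0.06 and a mean of 0.10 but camera's direction was down (BH-adjusted p = 0.707), with Olig1 at 0.06 and Olig2 at −0.01. Mesenchymal markers were at a median of −0.05 (camera, BH-adjusted p = 0.707, Pdgfra −0.31, Acta2 0.31), matrix genes at −0.06 (0.429, Ncan 0.06, Tnc −0.22) and endothelial markers at −0.10 (0.394, Ramp2 −0.19, Kdr −0.75). Interferon genes were at a median of 0.10 (camera, BH-adjusted p = 0.394, B2m 0.15) and Wnt genes at 0.08 (0.394, Ctnnb1 −0.05, Wnt5a 0.34).

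Deep-layer factors had a median of 0.05 and a mean of −0.03 with camera's direction up (BH-adjusted p = 0.713, Nfib 0.05, Etv1 0.16). Upper-layer factors were at a median of −0.02 (camera, BH-adjusted p = 0.770, Lmo4 −0.07, Cux1 0.08), ventral genes at 0.13 (0.698) and dorsal genes at −0.05 (0.688, Nr2f1 0.12, Wnt7b 0.76). Posterior genes had a median of −0.19 and a mean of 0.38 with camera's direction down (BH-adjusted p = 0.778). Their abundant members were Otx1 at −0.10 and Otx2, at 2.44 ± 3.27 CPM in E47wt and 15.9 ± 13.5 CPM in E47KO. This list takes in midbrain as well as hindbrain and spinal cord genes, so Otx2 alone shows no shift to posterior identity. Of the microglia markers only Cd68 was tested as a gene, at 0.05, and the erythroid list was not tested. Adjusted over each list alone, 1 gene was called, Xist as lower among the sex-linked genes.

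Whether a knockout effect differed between the lines was tested directly. No single gene passed with edgeR QL of 15277 tested, where 463 had an unadjusted p under 0.05 against 764 that chance gives, and DESeq2 called 1, Xist. This count was 306 without E12KO replicate 2, 799 without E47KO replicate 1 and 1804 without E47KO replicate 3. The effects on Tdg and Gm9855 differed by −0.12 ± 0.12 and −0.18 ± 0.37, those on Tcf3 by 0.21 ± 0.17, on Tcf4 by −0.09 ± 0.15, on Tcf12 by −0.08 ± 0.12 and on Cdkn1c by 1.18 ± 0.57, or by 0.51 without E47KO replicate 2. As a list, cholesterol genes had a lower effect in the E47 line in 19 of 19, by a median of −0.50 (camera, BH-adjusted p = 4.69e-06, p = 0.17 with an estimated correlation), and p53 targets in 16 of 18, by −0.29 (4.99e-05, p = 0.0459 with an estimated correlation). Lists of ER stress genes (−0.27, camera, BH-adjusted p = 0.00898, p = 0.263 with an estimated correlation), hypoxia and glycolysis genes (0.45, 0.00971, p = 0.303) and Notch genes (0.38, 0.0484, p = 0.289) also differed with the preset correlation. With an estimated correlation 0 lists passed after adjustment (camera, BH-adjusted p = 0.756 for each of the 5). Without E47wt replicate 2, 1 gene was called, and the difference for Gm9855 was 0.36. With sex as a covariate the difference for Gm9855 was −0.83 ± 0.29. The list tests between lines were not run with that covariate, although all E47KO libraries had Y-linked reads and of the other libraries only E47wt replicate 2 did.

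**Figure D5:**
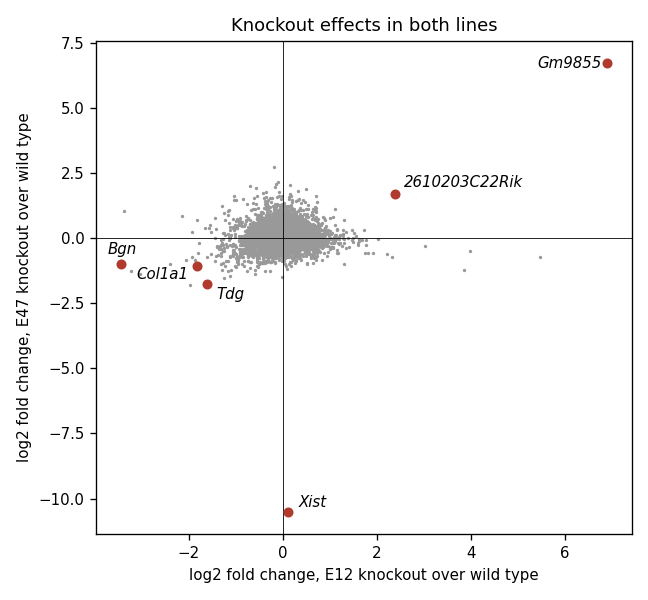
Fitted log2 fold changes of the genes tested in both lines, the E12 knockout on the horizontal and the E47 knockout on the vertical axis, one point per gene, with the called genes tested in both and Xist marked. Gm9855 and Tdg lie far from 0 in both lines.

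Across the 14614 genes tested in both lines, which are not independent replicates, the 2 sets of log2 fold changes correlated weakly (Pearson r = 0.083, Spearman rho = 0.032), and 51.4% had the same sign. The lines share no library. Gm9855 was called higher and Tdg lower in both, where lists that overlap at random would share 0.000137 and 0.000205 genes (Fisher's exact test, two-sided p = 0.000137 and 0.000205). The correlation was −0.045 without E47KO replicate 1 and 0.253 without E47KO replicate 2.

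The wild types of the lines were compared to measure what line, litter and culture add. No gene was called by edgeR QL of 14892 tested, with 568 at an unadjusted p under 0.05 against 745 that chance gives, and 9.39% of genes without overlap, where chance gives 10%. With the replicate block 1109 genes had an unadjusted p under 0.05 and none was called, and without E12wt replicate 2 there were 890. DESeq2 called 6, among them the mitochondrial gene mt-Co2 (−0.80 ± 0.12), Lynx1 (0.65 ± 0.14) and the gene model Gm15663 (−1.26 ± 0.15). Tcf3 differed by 0.13 ± 0.09, Tcf4 by 0.03 ± 0.08, Tcf12 by 0.01 ± 0.08, Cdkn1c by −0.41 ± 0.25 and Tdg by 0.04 ± 0.06 (E47wt over E12wt). The difference in Cdkn1c was −0.17 without E47wt replicate 3 and −0.69 without E47wt replicate 2. With the preset correlation, ribosomal protein genes (median 0.08, 25 of 26 above 0, camera, BH-adjusted p = 6.11e-05, p = 0.232 with an estimated correlation), p53 targets (0.11, 0.0196, p = 0.196) and axon guidance genes (0.11, 0.0196, p = 0.0284) were higher in E47wt. Hypoxia and glycolysis genes were lower in 22 of 25 (−0.28, camera, BH-adjusted p = 0.000806, p = 0.319 with an estimated correlation). With the replicate block, astrocyte markers (camera, BH-adjusted p = 0.00142) and interferon genes (0.0150) passed as higher too. With an estimated correlation 0 lists passed after adjustment, and axon guidance genes were at a camera BH-adjusted p of 0.781. With all 12 libraries in the fit, 1 gene was called.

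Genes next to Tcf3 were counted because a knockout chromosome can keep flanking sequence of another strain. Of the 100 tested neighbours on each side of Tcf3, taken in the order of the reference, Tdg was the only one called in either line, the 61st in the E12 and the 62nd in the E47 comparison. Gm9855 lay outside, 214 and 216 genes away on the other side. The share of called genes gave a two-sided Fisher's exact p of 0.0813 in E12 and 0.0274 in E47. In E47 it was 1 without E47wt replicate 1, E47wt replicate 3 or E47KO replicate 1, where Tdg was not called. At an unadjusted p under 0.05 were 15 of the 200 neighbours in E47 (7.5%, against 2.12% of the rest, Fisher's exact p = 3.63e-05) and 21 in E12 (10.5% against 8.79%, p = 0.379). Of these, 17 of 21 were below 0 in E12 and 12 of 15 above 0 in E47. Besides Tdg, and chosen after their values were seen, the neighbours Pcdh15 and 1190007I07Rik were below 0 and Polr3b above 0 in both lines among these. Fisher's exact test takes genes as independent, which neighbouring genes measured in the same libraries are not. Of 10 splits of the E47 libraries, the real one included, 3 had at least 15 neighbours at an unadjusted p under 0.05. The highest other split had 31.

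The authors' deposited tables list 12089 genes for E12, of which 62 have an adjusted p under 0.05 (27 higher, 35 lower), and 12561 genes for E47, of which 10 do (3 higher, 7 lower). All of these had the same sign and an unadjusted p under 0.05 in edgeR QL here, which called 4 of the 62 and 2 of the 10. DESeq2 on the same counts called 59 of the 62 and 5 of the 10. Across genes, the fold changes of the authors' deposited tables and those fitted here correlated at 0.990 in E12 and 0.992 in E47. Beyond the genes above, the authors' deposited table for E12 has lower values for the metalloprotease gene Adamts3 (−0.84), Id2 (−0.46), an inhibitor of E proteins, and Cdkn1c (−0.65, adjusted p = 0.0260), and higher ones for Lynx1 (0.76), Fosb (1.14) and Nptx1 (0.93). Their table for E47 has Xist (−10.41), Plxdc2 (−0.68), Diaph3 (−0.63), Grik3 (−0.78) and Cntn1 (−0.90) lower and Ccdc136 (0.53) higher; these genes were chosen from the authors' deposited table after its values were seen.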

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

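Every test of an explanation given here was chosen after the result was seen; the tests of the differences between the lines and of other groupings of the libraries were planned.

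Of the gene lists, 5 stood out because their knockout effect differed between the E47 and the E12 line with camera's preset correlation. The median difference, E47 minus E12, was −0.50 for cholesterol genes, −0.29 for p53 targets, −0.27 for ER stress genes, 0.45 for hypoxia and glycolysis genes and 0.38 for Notch genes. With an estimated correlation none of them passed after adjustment (camera, BH-adjusted p = 0.756 for each). Unadjusted camera p ran from 0.0459 for p53 targets to 0.303 for hypoxia and glycolysis genes. These tests between lines were not run with sex as a covariate or with a library left out. Sex-linked transcripts differed with genotype in the E47 line: all E47KO libraries had Y-linked reads, and of the E47wt libraries only replicate 2 did. In the E12 line alone, hypoxia and glycolysis genes were at a camera BH-adjusted p of 0.815 without E12wt replicate 3. In the E47 line alone, Notch genes were at 0.649 without E47KO replicate 2.

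Tdg was lower and Gm9855 higher in every knockout library of both lines, by nearly the same amount. Gm9855 matches the Tdg mRNA over all of its 1194 bases at 99.2% identity and covers 40.4% of an mRNA of 2959 bases and 34.1% of another of 3502 bases. If all reads that left Tdg fell evenly on a copy counted over that stretch, Gm9855 should gain one of these shares of the loss. The gain was 40.4% of the loss at Tdg in E12 (36.3 to 43.1% over pairs of libraries) and 38.0% in E47 (31.5 to 43.6%). The shorter mRNA lies in both ranges and the longer one in that of E47 alone. The summed CPM of Tdg and Gm9855 fell from 175 ± 5.35 to 105 ± 3.71 in E12 and from 180 ± 4.06 to 102 ± 9.96 in E47. A move of every lost read to the other gene would keep this sum, so its fall argues against that form alone. A gain of only one of the shares above lowers the sum too, so the fall does not test such a gain. Whether Tdg-like reads fell where neither gene was counted was not tested, so a change of that form stays open. Sequence of another strain around Tcf3 in both knockouts may be a source of the change at Tdg and Gm9855. Fold changes of the 200 neighbours, with Tdg and Gm9855 left out beforehand, correlated between the lines at 0.252 (Spearman rho 0.150). This was above 95.1% of 9719 other windows (95th percentile 0.250), which overlap, with 60 side by side. The margin is so narrow that the test barely decides. Of the neighbours at an unadjusted p under 0.05, 17 of 21 were below 0 in E12 and 12 of 15 above 0 in E47. These tallies rest mostly on different genes, so they cannot test an effect of such sequence shared by the lines. Besides Tdg, the genes in both sets had the same sign in both lines. Pcdh15 (−1.32 in E12, −0.98 in E47) and 1190007I07Rik (−0.99, −1.08) were below 0, and Polr3b (0.30, 0.28) was above 0. The correlation goes with a shared effect by a narrow margin only, so this explanation stays undecided. Loss of either isoform cannot be told apart from such sequence. The lowest knockout value of Gm9855 was 61.2 times the highest wild-type one, and every knockout library carries both the lost isoform and the altered chromosome.

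Col1a1, Col1a2, Bgn and other genes of fibroblast matrix were lower in E12KO. On a list of 30 fibroblast genes, all found and 24 of them tested, 10 were lower at an unadjusted p under 0.05 (9 of these had been seen before listing), 3 were higher and 11 were neither; 10 of the 30 are also expressed at 1 CPM or more in all libraries, 10 are on the mesenchymal list and 8 on the matrix list. RNA of fibroblast-like cells in some libraries is a candidate explanation: the median of the 10 lower genes was 1.67 CPM in E47wt replicate 1 and 0.0852 CPM in replicate 3, a ratio of 19.6 within one wild-type group, while over all 30 listed genes it was 1.67 and 0.426 CPM. Of these 10, Col1a1 was the most abundant there at 6.885 CPM, and Lum and Dcn, listed but not among the 10, were at 0.109 and 0.272 CPM. Loss of E12 stays open for the E12 line: with E12 intact, 1 of the 3 E47wt libraries was at or below the highest E12KO median of 0.200 CPM, replicate 2 was just above it at 0.235 CPM, and the E47KO libraries, which lack E47, were at 0.156, 0.471 and 0.180 CPM, so low levels occur without loss of E12 and the explanations cannot be told apart.

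Xist was high in 2 of the 3 E47wt libraries and near 0 in E47KO. Low Xist occurred without loss of E47 in E47wt replicate 2 (0.835 CPM), but that library also had Y-linked reads (245 CPM). Since every E47KO library had Y-linked reads too (200 to 240 CPM), an effect of E47 loss on Xist cannot be told apart from sex. The sex of the embryos may account for it: all 12 libraries had either Xist or the Y-linked genes above 100 CPM and never both.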

How the results depend on the processing

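Fits with robust empirical Bayes, a sex term, Y-linked libraries alone, sex chromosomes left out, DESeq2 on both-strand counts, other neighbour numbers, libraries left out of list, neighbour and correlation results, and the replicate block in the list tests between lines and between wild types were chosen after the data were seen. The 6 genes of the E12 knockout became 95 with DESeq2, 94 with DESeq2 on both-strand counts, 20 without a low-count filter, 2 with all 12 libraries in the fit and 2 to 10 with a library left out (2 without E12KO replicate 2 or 3, 10 without E12wt replicate 3). The 2 of the E47 knockout became 5 with either DESeq2 fit, 1 with a sex covariate, 0 with the libraries that have Y-linked reads alone and 0 to 7 with a library left out. Between lines, 0 became 1 with either DESeq2 fit and 0 to 1 with a library left out; between wild types, 0 became 6 with DESeq2, 15 with DESeq2 on both-strand counts and 1 with all 12 libraries, and stayed 0 with each library left out. The sex covariate, the Y-linked libraries alone and left-out libraries leave fewer libraries or degrees of freedom. Counts also rose with a library left out, to 10 without E12wt replicate 3 and to 7 without E47wt replicate 2. The cause of these changes was not tested. RLE factors, the 1 CPM filter, both-strand counts, robust empirical Bayes and, in E47, sex chromosomes left out kept each of these counts within 1.5 times.

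Replicate numbers did not pair the E12 libraries (correlations 0.18, 0.11 and −0.11); a replicate block left 4 E12 genes and 10 lists, and 6 E47 lists. It raised the lists that passed from 5 to 6 between lines (axon guidance genes, camera, BH-adjusted p = 0.0268) and from 4 to 6 between wild types, and changed no other call of genes or lists in these comparisons. With the block and an estimated correlation, 0 lists passed in either comparison (axon guidance genes between lines, camera, BH-adjusted p = 0.698). The 11 E12 lists became 0 with an estimated correlation, 1 with fry, 3 with fry in either direction and 7 to 12 with a library left out; the 7 E47 lists became 0, 0 and 0, 4 with a sex covariate and 3 to 9. The correlation of both effects was 0.964 over the 5 called genes, which were picked for large effects, and 0.0415 without them, and it ran from −0.045 to 0.253 with a library left out; the cause was not tested. Fisher's exact test of the neighbours of Tcf3 in E47 gave p = 1 with 50 and 0.0545 with 200 neighbours on each side, and 0.0270 to 1 with a library left out; in E12 it gave 0.0274 to 0.130. Calls shared with the authors' deposited tables rose from 4 to 59 with DESeq2 and 60 with both-strand counts too in E12, and from 2 to 5 and 4 in E47. Tcf3 kept its sign in all fits, at 0.08 to 0.30 in E12 and 0.31 to 0.50 in E47 with a library left out. No called gene that the text names by the fixed rule changed sign; among all 1297 values of these genes in E12 and 1634 in E47, 46 and 106 were sign changes of a gene called in neither fit. Megabase windows around Tcf3 were not run.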

Other observations

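Other groupings of the libraries were a planned test; the genes, strands and liver genes described here were chosen after their values were seen.

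DESeq2 called 38 genes higher and 57 lower in E12KO, where edgeR QL called 6. The 38 include Serpina1e, Mup7, Slco1a1 and Cyp2d9, which are on the list of male liver genes below. Single genes among the higher ones were the immediate early gene Fosb at 1.13 ± 0.18 (DESeq2, BH-adjusted p = 1.35e-06) and the synaptic organizer Nptx1 at 0.93 ± 0.16 (1.00e-05). Others were Hsd17b7, an enzyme of cholesterol synthesis, at 0.55 ± 0.13 (DESeq2, BH-adjusted p = 0.00672), and Thrsp, a regulator of fatty acid synthesis, at 1.15 ± 0.24 (0.00136). Lower were Id2, which binds E proteins (−0.46 ± 0.09; 0.000619), the oligodendrocyte factor gene Zfp488 (−1.06 ± 0.22; 0.00136), the myelin glycoprotein gene Omg (−0.67 ± 0.16; 0.0116), the neurofilament gene Nefm (−0.58 ± 0.15; 0.0244) and the Wnt antagonist gene Sfrp1 (−0.41 ± 0.09; 0.0024). The matrix genes Lox, Postn and Col3a1 were at −3.25, −4.09 and −4.34 on the log2 scale. Serpina1e, Mup7 and Slco1a1 were removed by the low-count filter and not tested with edgeR QL, and none of the other genes named here reached an adjusted p under 0.05 with it.

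Adamts3 and Lynx1 had the same sign in both lines and were called by edgeR QL in neither. Adamts3, which encodes a procollagen-cleaving protease, was at −0.83 ± 0.11 in E12 (edgeR QL, BH-adjusted p = 0.0686) and −1.07 ± 0.28 in E47 (0.971), and Lynx1, a modulator of nicotinic receptors, at 0.76 ± 0.10 (0.0686) and 0.42 ± 0.14 (0.971). 2610203C22Rik was at 0.471 ± 0.0620 CPM in E47wt and 1.55 ± 0.646 CPM in E47KO (1.72 ± 0.39; edgeR QL, BH-adjusted p = 0.971). Reads on the sense-strand column, which the comparisons did not use, gave 0 called genes with edgeR QL in either line (243 at an unadjusted p under 0.05 in E12 and 124 in E47; DESeq2 was not run on it). The top genes there were Gm16277 (−0.91), Vxn (2.83) and Adhfe1 (2.15) in E12, with an edgeR QL BH-adjusted p of 0.111, 0.111 and 0.123.

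Reads on genes of the liver were present in the libraries of these neural cultures. Whether these reads came from the cultured cells was not tested. On a list of 30 liver genes, 29 or 30 had more than 3 reads in every library except E12wt replicate 3, where 9 did. Their sum was 2.5 CPM in that library, 66.7 to 75.5 CPM in the other E12 libraries and 130 to 190 CPM in the E47 libraries, and Alb alone was at 0.254 CPM, 30.8 to 42.5 CPM and 66.5 to 101 CPM. On a list of 13 genes of male liver, including Mup20 and Cyp2d9, 10 to 12 had more than 3 reads in E12KO replicates 1 to 3, E47wt replicates 2 and 3 and E47KO replicate 1, and 2 to 5 did in the other libraries. Reads on this list did not follow the sex-linked transcripts. The Y-linked genes summed to at most 0.362 CPM in the E12KO libraries and E47wt replicate 3. They summed to 240 and 200 CPM in E47KO replicates 2 and 3, where few of the 13 genes passed 3 reads.

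Other splits of the libraries cannot show whether chance is excluded in the comparisons of 3 with 3 libraries, since 10 splits give no share under 0.05. Called genes numbered 6 in E12 against 0 in the highest other split (1 split of 10 as high), 2 in E47 against 1 (1 split) and 0 between wild types against 0 (10 splits). Lists passing numbered 11 against 8 in E12 (1 split) and 7 against 9 in E47 (3 splits), and neighbours of Tcf3 at an unadjusted p under 0.05 numbered 21 against 37 in E12 (2 splits) and 15 against 31 in E47 (3 splits). For the interaction, 100 of 100 splits drawn from 200 had at least the real count of 0, and the highest other gave 5. Any split reaches a real count of 0, here and between wild types, so these counts decide nothing. The size of the correlation of effects, 0.083, was reached in 63 of 100 splits, with a highest other of 0.308, so chance is not excluded for it.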
